A study of Mus musculus with 27 samples.

How the data were processed

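Total RNA from dissected mouse cortex was sequenced at embryonic day (E) 13.5, at E15.5 and on the day of birth (P0). The 27 libraries were made from control (wild-type) animals, from animals in which Emx1-Cre recombined a floxed Bcl11a gene (Bcl11a-CKO), and from animals in which it recombined floxed Bcl11a and Bcl11b (Bcl11ab-DCKO), with 3 libraries in each of 9 groups. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.0, edgeR without a version, and the mouse genome build mm10, without saying what each did. Counting settings, strandedness and filters are not given in the sources used here.

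The embryonic table holds whole-number read counts per gene, as deposited by the authors, for 34745 genes in 18 libraries, with totals of 4313142 to 7220708 counts. The P0 libraries stand in one table per mutant, each with the same control libraries. Per the file headers, the authors gave CPM per library there, with an average log2 CPM and a log2 fold change. That log2 fold change by the authors is mutant minus control in the Bcl11a-CKO table and control minus mutant in the Bcl11ab-DCKO table, and it was not used for any result. In the P0 tables, 99.963% and 99.952% of the CPM values were whole multiples of 1 read (tolerance 0.00051 CPM), which gave library sizes of 16367280 to 25693593 reads. These tables list 13423 and 7999 genes, of which 7346 stand in both.

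The genes missing from the P0 tables are not missing at random. With the p of edgeR's exact test on the recovered reads of the Bcl11a-CKO table, 70 genes lay at or under 6.8e-22, none lay between that value and 0.00019, and the rest lay above. In the Bcl11ab-DCKO table, 70 genes lay at or under 3.4e-26 and the rest at or above 0.054. The range in which this gap was searched was set after seeing the data. Genes with p-values in the gap are not analysed here, so P0 counts are counts among the genes held and not the number of genes that changed.

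Samples were put in groups from their titles. At E15.5, control replicates 2 and 3 share a title number and carry the letters R and L, as do Bcl11a-CKO replicates 2 and 3. Each pair was read as the sides of 1 animal and summed into 1 unit, which left 16 embryonic units, with 2, 2 and 3 at E15.5. The chi-square value per gene between the libraries of these pairs was 3.66 and 3.83, against 5.13 to 15.1 for the other pairs within a group, where sampling noise alone gives 1. No libraries held identical values, and 0 columns were left without a sample. The sources used here do not tie each library to an animal, so p-values measure the spread between these samples, which may in part be technical.

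Embryonic counts were fitted with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) in one model with 6 groups, after TMM scaling and the filterByExpr filter, which kept 14947 genes. The common biological coefficient of variation was 0.139. At P0, limma (3.58.1) with a mean-variance trend was fitted to log2(CPM + 1) of genes with a mean of at least 1 CPM, in each table by itself, so a P0 fold change is on the log2(CPM + 1) scale and understates the change of low genes. The mutants were compared at P0 over the genes listed in both tables, from all 9 libraries. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, at 0.05, and every adjusted p in the text comes from edgeR (embryonic) or limma (P0 and gene lists). At P0 only the genes held could be tested, so each adjusted p there depends on which genes are missing and is no error rate over all genes. In the P0 Bcl11a-CKO, 3679 of 12576 genes had an unadjusted limma p under 0.05, and 70 passed after adjustment. Embryonic group means are CPM after TMM scaling, with factors from the filtered genes, or from all genes for the means of mt-Atp8, Hba-a2 and Malat1. The plots show CPM per library with factors from all genes in the embryo, and ± stands for the SD of a mean or the SE of a log2 fold change.

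Of the 25 gene lists fixed before the data were examined, 22 entered limma's camera with an inter-gene correlation of 0.01, over 8 embryonic comparisons, adjusted over all 176 tests. The deleted genes, the sex-linked genes and choroid plexus, none of whose genes was tested in the embryo, did not enter. Of 40 calls, 2 held with an estimated correlation, both for layer 6 corticothalamic neurons at E15.5 in the Bcl11ab-DCKO, against the control and against the Bcl11a-CKO. Camera was planned at P0 too and was not run there, because genes are missing from those tables by their p-value.

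The design, the tests, the list of alternatives and the rule for naming genes were set before the data were examined. For each comparison with the control, the rule took both deleted genes, the 8 genes that rose and the 8 that fell most among those past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries, and up to 4 members of each list. For comparisons between the mutants and between ages it took 5 genes in each direction, and for the latter the libraries had to separate at E15.5 or E13.5. Predicted, unnamed and sex-linked genes were left out, and a few genes that the rule took are not reported here. Genes named outside the rule are the mitochondrial, globin and sex-linked genes, Malat1 and the meningeal genes at P0, chosen after their values were seen.

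Gene identifiers were matched to GENCODE release M21, on the same build. It held 34267 of the embryonic identifiers, 27699 of them with equal coordinates, and 13393 and 7979 of those in the P0 tables. There were 65 duplicated gene names. Because strand is not given, the reads of genes that share exonic bases cannot be told apart, and such genes are uncertain. Genes whose sequence is shared with others are uncertain too. As a measure added after seeing the data, the percentage of a gene's transcript 31-mers (1 in 16 sampled, at least 5 needed) that also stand in transcripts of another gene was computed, with 50% as the limit.

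The scripts were tested on simulated data with 200 changed genes, 100 at 2-fold and 100 at 4-fold. The changed genes were drawn only from those above a minimum mean, so the recovery does not cover the lowest genes tested. No simulated P0 gene was left out by its p, so the P0 values do not mimic the gap in the P0 tables. At E13.5, the Bcl11a-CKO comparison recovered 73% of the 2-fold and 97% of the 4-fold changes with 9 false calls among 14947 genes, and the Bcl11ab-DCKO comparison 75% and 97% with 7. At E15.5 the values were 59% and 89% with 5 false calls for the Bcl11a-CKO, and 73% and 97% with 4 for the Bcl11ab-DCKO. At P0 they were 88% and 100% with 14 among 13423 genes, and 83% and 100% with 16 among 7999.

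Alternatives were DESeq2 (1.42.0), its size factors, other filters on low values (none, or 10 CPM for counts and 5 for CPM), a pseudocount of 0.1, a log2 fold change of at least 1, the libraries of 1 age alone, each library as its own replicate, replicate blocks, and leaving out each library or unit in turn. Added after seeing the data were edgeR on the recovered P0 reads, P0 tests without genes that overlap or share sequence, and E13.5 tests without the control and Bcl11a-CKO libraries nearest to E15.5 on the first principal component. The pseudocount was not applied to counts, the single-age fit not to comparisons between ages. Where a group had counts of 0 in all libraries, its fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% interval; these intervals and floors cover counting error only.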

Results

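Bulk RNA sequencing was done on cortex of control mice, of Bcl11a-CKO mice and of Bcl11ab-DCKO mice at E13.5, E15.5 and P0. Bcl11a and Bcl11b are zinc-finger transcription factors, and Emx1-Cre acts in the progenitors of the dorsal telencephalon, which give rise to the projection neurons of the cortex. The study asked what these factors do in the production and differentiation of these neurons. Each group had 3 libraries. Counts per library ran from 4313142 to 7220708 in the embryo, and the reads recovered at P0 ran from 16367280 to 25693593. After summing the E15.5 pairs that share a title number, n was 3 in each E13.5 and P0 group, 2 in the E15.5 control and Bcl11a-CKO groups, and 3 in the E15.5 Bcl11ab-DCKO group. On principal components of the embryonic libraries, the first (56.4% of the variance) separated the ages and the second (12.4%) ran from control to Bcl11ab-DCKO. At E13.5, control replicate 2 and Bcl11a-CKO replicate 1 lay nearest to E15.5 on the first component.

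Bcl11b (ENSMUSG00000048251, chromosome 12, 107910403 to 108003602, mm10) was far lower in the Bcl11ab-DCKO at each age and was not lowered in the Bcl11a-CKO embryo. At E13.5 its mean was 222.7 ± 93.4 CPM in the control, 290.0 ± 84.1 in the Bcl11a-CKO and 50.7 ± 6.38 in the Bcl11ab-DCKO (n = 3 each), a log2 fold change of -2.14 ± 0.25 in the double mutant (edgeR, adjusted p = 0.000121). At E15.5 it fell from 328.2 ± 6.12 to 109.3 ± 8.49 CPM (log2 fold change -1.59 ± 0.26, adjusted p = 0.000674), and at P0 from 204.3 ± 32.3 to 38.5 ± 3.90 CPM (-2.37 ± 0.12, limma, adjusted p = 7.35e-06). Bcl11a (ENSMUSG00000000861, chromosome 11, 24078056 to 24174123) moved less. It fell at E13.5 from 487.3 ± 52.3 CPM to 319.3 ± 55.8 in the Bcl11a-CKO (-0.61 ± 0.11, adjusted p = 0.00764) and to 299.8 ± 16.7 in the Bcl11ab-DCKO (-0.70 ± 0.11, adjusted p = 0.00101). At E15.5 its change did not pass the test in the Bcl11a-CKO (-0.39, adjusted p = 0.189) or the Bcl11ab-DCKO (-0.12, adjusted p = 0.563), nor at P0 in the Bcl11a-CKO (0.22 ± 0.14, adjusted p = 0.315). The labels do not say which part of either gene is deleted, so a count over the whole gene does not check the deletion of a part. Bcl11a shares exonic bases with a neighbouring transcript, 4930538E20Rik. Genes named below that share them too, and are uncertain in that respect, are Eomes, Hes5, Notch1, Ccnd2, Cdkn1a, Pcp4, Crim1, Hs3st4, Sox5, Syt6, Tmem163, Pou3f1, Plxna4, Nrp1, Unc5c, Ephb1, Neurod1, Nefl and Slc32a1. So are Ppp1r1b, Prox1, Rspo3, Lef1, Ebf3, P2ry12, Csf1r, Col3a1, Jakmip3, Ryr3, Nexn, Ddn, Fgfr1, Rasa4, Xist and Malat1, and others are marked where they come up. Bcl11b in the P0 Bcl11a-CKO and Bcl11a in the P0 Bcl11ab-DCKO were not analysed here.

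**Figure D1:**
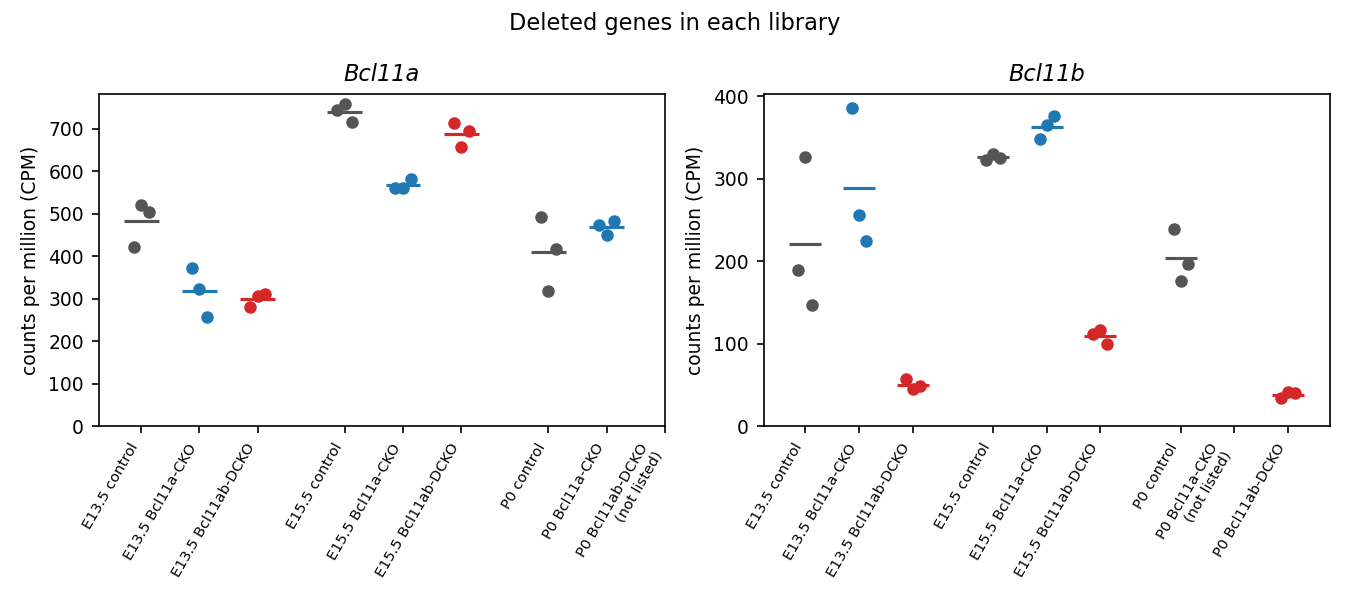
CPM of Bcl11a (left) and Bcl11b (right) on linear axes from 0, with a point for each library and a bar for each group mean, by age and genotype. Bcl11b lies lowest in the Bcl11ab-DCKO at each age, with a group mean of 38.5 CPM at P0.

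In the E13.5 Bcl11a-CKO, Eomes and Slc17a6 rose and Hopx fell. Eomes, the transcription factor that marks intermediate progenitors, rose from 396.4 ± 82.1 to 706.5 ± 12.6 CPM (n = 3 each, log2 fold change 0.83 ± 0.11, edgeR, adjusted p = 0.00132). Slc17a6, the vesicular glutamate transporter of early excitatory neurons, rose from 68.5 ± 11.2 to 139.0 ± 8.25 CPM (1.02 ± 0.11, adjusted p = 0.000425). Hopx, a marker of radial glia that shares exonic bases with Hopxos, was the gene that fell most among those named, from 10.3 ± 5.02 to 1.33 ± 1.08 CPM (-3.01 ± 0.59, adjusted p = 0.0147). In all, 257 genes rose and 130 fell of 14947 tested.

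The largest rises were those of Fignl2, a member of the AAA ATPase family (6.04 against 0.895 CPM, log2 fold change 2.73 ± 0.26, adjusted p = 9.73e-05), the adhesion receptor gene Adgra1 (2.63 ± 0.26), Ppp1r14c (30.7 against 4.96 CPM, 2.63 ± 0.24), and Gjd2, which encodes the gap junction protein connexin 36 (2.61 ± 0.32). Klhl35, Wscd2, Zcchc24 and the collagen gene Col22a1 followed with log2 fold changes of 2.31, 2.29, 2.25 and 2.05, and Zcchc24 went from 17.3 ± 3.25 to 82.3 ± 4.33 CPM. After Hopx, the largest falls were those of Fam181a (-2.04 ± 0.42), the secreted Wnt antagonist gene Frzb (-2.01 ± 0.34, adjusted p = 0.00634), Rnd1 (-1.92 ± 0.29) and Rprd1b (-1.88 ± 0.36). Myo1d, the Notch target Hey2 and the pro-apoptotic gene Hrk fell by 1.82, 1.80 and 1.62 on the log2 scale. Ppp1r14c, Gjd2, Col22a1 and Rprd1b share exonic bases with another gene and are uncertain.

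Of the 12 intermediate progenitor genes, 3 rose and none fell (6 rose and 1 fell adjusted over the list alone): Eomes, and the Notch ligand gene Dll3 (0.77 ± 0.16) and the somatostatin receptor gene Sstr2 (0.66 ± 0.15). The list was higher as a set by camera (adjusted p = 0.000616), and adjusted p = 0.42 with an estimated correlation. Of 16 radial glia genes, Hopx and the Notch target Hes5 (-0.65 ± 0.16) fell and none rose (6 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0132, and adjusted p = 0.652 with an estimated correlation). None of 26 cell cycle genes passed the test, alone or adjusted over the list alone, while the list was lower as a set (adjusted p = 0.000352, and adjusted p = 0.775 with an estimated correlation). Of 15 upper-layer genes, the transcription factor gene Pou3f2 (0.75 ± 0.10) and the netrin receptor gene Unc5d (1.06 ± 0.24) rose (6 rose adjusted over the list alone; adjusted p = 0.0217, and adjusted p = 0.558 with an estimated correlation). Of 28 axon guidance genes, Sema3c (1.47 ± 0.23), Plxna4 (0.96 ± 0.19) and Nrcam (0.61 ± 0.13) rose (7 rose and 2 fell adjusted over the list alone; adjusted p = 0.0188, and adjusted p = 0.683 with an estimated correlation). Of 16 pan-neuronal genes, Slc17a6 and Dcx (0.70 ± 0.15), a microtubule protein gene of migrating neurons, rose (2 adjusted over the list alone; adjusted p = 0.0417, and adjusted p = 0.778 with an estimated correlation). Of 5 thalamus genes, Slc17a6 rose (2 adjusted over the list alone; adjusted p = 0.0132, and adjusted p = 0.181 with an estimated correlation). The 16 GABAergic interneuron genes were higher as a set with no gene past the test (1 rose adjusted over the list alone; adjusted p = 0.0377, and adjusted p = 0.765 with an estimated correlation).

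Single members moved in other lists of the E13.5 Bcl11a-CKO, with no call for the set. Fezf2, the transcription factor of layer 5 subcerebral neurons, fell (-0.44 ± 0.10, 1 of 10; 2 rose and 2 fell adjusted over the list alone), as did Zfpm2 of layer 6 (-0.83 ± 0.17, 1 of 9; 1 rose and 1 fell) and Reln of Cajal-Retzius neurons (-0.58 ± 0.13, 1 of 8; 1 rose and 2 fell). The transcription factor gene Ebf1 of the striatal list rose (1.69 ± 0.25, 1 of 8; 1 adjusted over the list alone), and so did Tmem163 of the subplate (0.84 ± 0.16, 1 of 6; 1). Of 7 astrocyte genes, Aldh1l1 rose and Aldoc fell (3 rose and 1 fell adjusted over the list alone). No gene passed the test among 15 p53 and apoptosis genes, 5 of the hippocampus and cortical hem, 6 of the oligodendrocyte lineage, 11 of microglia, 9 of endothelium and pericytes, 7 meningeal, 8 erythroid and 7 immediate early genes. Adjusted over the list alone, 1 hippocampal gene fell.

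Leaving out control replicate 2 or 3 lowered the count for the E13.5 Bcl11a-CKO from 387 to 205 or 184, and 162 genes passed without control replicate 2 and Bcl11a-CKO replicate 1, an alternative added after seeing the data. Eomes, Slc17a6, Pou3f2, Sema3c, Ebf1 and the 8 genes that rose most kept their calls whichever library was left out. Hopx did not pass without Bcl11a-CKO replicate 1, Bcl11a-CKO replicate 2 or control replicate 2 (adjusted p = 0.0526, 0.0621 and 0.0664). Without control replicate 3 the adjusted p was 0.105 for Dll3, 0.153 for Sstr2, 0.158 for Unc5d, 0.162 for Hes5, 0.119 for Dcx, for Hey2 and for Aldh1l1, 0.121 for Fezf2, 0.102 for Fam181a, 0.0903 for Nrcam, 0.0772 for Reln, 0.0675 for Plxna4 and 0.0531 for Zfpm2. Aldoc did not pass without control replicate 2 (adjusted p = 0.0523).

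In the E13.5 Bcl11ab-DCKO Eomes rose too, and Zfpm2 and Fezf2 fell. Eomes went from 396.4 ± 82.1 to 814.6 ± 49.6 CPM (log2 fold change 1.04 ± 0.11, edgeR, adjusted p = 6.35e-05, n = 3 each). Zfpm2, a transcriptional cofactor gene of corticothalamic neurons, fell from 35.3 ± 7.46 to 11.5 ± 0.677 CPM (-1.61 ± 0.18, adjusted p = 9.54e-05). Fezf2 fell from 165.9 ± 9.28 to 97.7 ± 12.6 CPM (-0.76 ± 0.10, adjusted p = 0.000369). In all, 569 genes rose and 485 fell of 14947 tested.

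Scube2, which encodes a secreted protein of Hedgehog signalling, had 216 counts in the E13.5 Bcl11ab-DCKO and 1 in the control, a ratio of 189 (95% interval 33.5 to 7490). Fignl2 rose from 0.895 ± 0.495 to 22.2 ± 0.972 CPM (4.61 ± 0.23, adjusted p = 1.16e-07) and Wscd2 from 4.02 ± 1.53 to 57.6 ± 4.61 CPM (3.84 ± 0.21, adjusted p = 2.33e-07). The embryonic myosin gene Myh3, the sulfotransferase gene Hs3st3a1, the prostaglandin D2 synthase gene Ptgds, Rgl3 and Prtg rose with log2 fold changes of 4.44, 3.93, 3.90, 3.84 and 3.73. Among the genes that fell, Kcna1, a voltage-gated potassium channel gene, had 3 counts in the mutant and 82 in the control (control over mutant 31.3, 95% interval 10.3 to 155). The sulfonylurea receptor gene Abcc8 fell from 23.8 ± 15.7 to 0.506 ± 0.368 CPM (-5.52 ± 0.87, adjusted p = 0.00127). Myo1h (-5.73 ± 1.43), Cnnm1 (-4.32), the desmosomal gene Dsp (-4.26), the protease gene Pappa2 (-3.95), the extracellular matrix gene Tnr (-3.87) and the dynein chain gene Dync1i1 (-3.78) fell too. Myo1h shares exonic bases with Kctd10, and Hs3st3a1, Cnnm1, Dsp, Pappa2 and Tnr share them with less known transcripts, so these are uncertain.

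Of the 12 intermediate progenitor genes 6 rose (6 adjusted over the list alone), among them Dll3 (1.27 ± 0.16), Hes6 (0.32 ± 0.07) and Mfng (0.36 ± 0.09), and the list was higher as a set (camera, adjusted p = 2.84e-05, and adjusted p = 0.34 with an estimated correlation). Of the 9 layer 6 genes 3 fell (6 adjusted over the list alone): Zfpm2, Sox5 (-0.86 ± 0.20), and the heparan sulfate sulfotransferase gene Hs3st4, at 62 counts in the control and 0 in the mutant, at least 23.6-fold lower. The set was lower (adjusted p = 6e-04, and adjusted p = 0.356 with an estimated correlation). Of 10 layer 5 genes Fezf2, Pcp4 (-2.14 ± 0.32) and Crim1 (-0.65 ± 0.13) fell (3 adjusted over the list alone; adjusted p = 0.037, and adjusted p = 0.25 with an estimated correlation). Slc17a6 of the thalamus list rose (1.29 ± 0.11, 1 of 5; 2 adjusted over the list alone; adjusted p = 0.0135, and adjusted p = 0.181 with an estimated correlation).

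Other lists of the E13.5 Bcl11ab-DCKO had no call for the set. Of 15 upper-layer genes 3 rose and 3 fell (4 and 3 adjusted over the list alone), with Pou3f2 up (0.71 ± 0.10). Of 28 axon guidance genes 5 rose and 4 fell (9 and 6), with Unc5c (1.92 ± 0.22) and Sema3c (1.43 ± 0.24) up and Flrt2 (-0.94 ± 0.13) and Nrp1 (-1.14 ± 0.19) down. Of 16 pan-neuronal genes 2 rose and 4 fell (3 and 8), with Slc17a6 up and Slc17a7, the glutamate transporter of later cortical neurons, down (-1.43 ± 0.16). Radial glia had 1 gene up, Notch1 (0.37 ± 0.08), and 2 down, Hopx and Nes, of 16 (2 and 2). Cdkn1a, a target of p53, rose (0.88 ± 0.18) and Zmat3 fell (-0.37 ± 0.09) among 15 p53 and apoptosis genes (1 and 1). Rspo3 (-2.10 ± 0.45) and Prox1 (-1.34 ± 0.31) of the hippocampus and cortical hem fell (2 of 5; 2). Tmem163 of the subplate rose (1.21 ± 0.16, 1 of 6; 1). Ebf1 rose and Ppp1r1b fell in the striatal list (2.16 ± 0.25 and -1.75 ± 0.43; 2 and 2 adjusted over the list alone). Lhx5 rose and Reln fell among Cajal-Retzius genes (0.96 ± 0.24 and -0.95 ± 0.13; 1 and 1), and Aldh1l1 rose and Aldoc fell among astrocyte genes (2.95 ± 0.71 and -1.14 ± 0.15; 2 and 1). Olig2 of the oligodendrocyte lineage fell, with 39 counts in the control and 1 in the mutant, a ratio of 44.6 (95% interval 7.55 to 1810; 1 of 6; 1). No cell cycle, GABAergic, microglial, endothelial, meningeal, erythroid or immediate early gene passed the test.

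The count of 1054 genes fell to 614 without control replicate 2, to 692 without control replicate 3 and to 670 without Bcl11ab-DCKO replicate 3. Of the 55 called genes that the naming rule took, 41 kept their calls whichever library was left out and 14 lost them at least once, not all of them listed here. Without control replicate 2 the adjusted p was 0.0757 for Hes6, 0.102 for Mfng, 0.0995 for Sox5, 0.0962 for Nes, 0.115 for Ppp1r1b, 0.106 for Lhx5, 0.0802 for Aldh1l1, 0.0703 for Myo1h, 0.0611 for Hs3st3a1 and 0.0594 for Olig2, and Zmat3 and Prox1 did not pass without Bcl11ab-DCKO replicate 1 (0.08 and 0.0709).

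Set against each other at E13.5, the mutants differed in few genes: 45 were higher and 64 lower in the Bcl11ab-DCKO than in the Bcl11a-CKO (n = 3 each, edgeR, 14947 tested). Scube2 was higher in the double mutant (12.1 ± 1.42 against 1.11 ± 0.331 CPM, log2 fold change 3.40 ± 0.28, adjusted p = 0.000115), as were Prtg (2.83), Myh3 (2.65), Rgl3 (2.49) and the homeobox gene Uncx (2.08). Bcl11b (-2.52 ± 0.25, adjusted p = 0.000348), Abcc8 (-4.49), Dync1i1 (-3.27), Tnr (-3.24) and the nuclear receptor gene Nr4a3 (-2.90) were lower. The layer 6 set was lower (0 of 9 genes past the test, 4 adjusted over the list alone; camera, adjusted p = 3.21e-05, and adjusted p = 0.25 with an estimated correlation). So was the pan-neuronal set (1 of 16, and 7; adjusted p = 1.05e-06, and adjusted p = 0.486 with an estimated correlation). The layer 5 (adjusted p = 0.037, and adjusted p = 0.25 with an estimated correlation) and upper-layer sets (adjusted p = 0.037, and adjusted p = 0.608 with an estimated correlation) were lower. The cell cycle (adjusted p = 0.0463, and adjusted p = 0.81 with an estimated correlation) and erythroid sets (adjusted p = 0.0395, and adjusted p = 0.683 with an estimated correlation) were higher. The count of 109 genes went to 63 without Bcl11a-CKO replicate 2, 209 without Bcl11a-CKO replicate 3, and 41, 37 and 52 without Bcl11ab-DCKO replicates 1, 2 and 3. Without Bcl11ab-DCKO replicate 2 the adjusted p was 0.215 for Abcc8, 0.11 for Dync1i1, 0.101 for Myh3, and 0.139 for Tnr and for Nr4a3.

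At E15.5, Reln, Nr4a2 and Tle4 fell and Slit2 rose in the Bcl11a-CKO. Reln, the secreted protein of Cajal-Retzius neurons, fell from 463.6 ± 21.0 to 207.0 ± 28.9 CPM (n = 2 each, log2 fold change -1.17 ± 0.15, edgeR, adjusted p = 0.00163). Nr4a2, a nuclear receptor gene of subplate and layer 6b neurons, fell from 31.5 ± 1.10 to 8.14 ± 0.765 CPM (-1.93 ± 0.30, adjusted p = 0.00479), and the corticothalamic gene Tle4 from 209.5 ± 30.4 to 93.7 ± 5.43 CPM (-1.16 ± 0.15, adjusted p = 0.00137). The guidance cue gene Slit2 rose from 11 ± 0.305 to 24.0 ± 2.05 CPM (1.11 ± 0.12, adjusted p = 0.00038). In all, 186 genes rose and 103 fell of 14947 tested.

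By fitted log2 fold change the rises were led by Cdh23, an atypical cadherin gene (16.9 ± 16.8 against 0.793 ± 0.294 CPM, 4.33 ± 0.85, adjusted p = 0.0174). Its units in the mutant lay far apart, so its rank is uncertain. Next was Dhrs3, a retinaldehyde reductase gene (23.3 ± 0.703 against 2.47 ± 0.184 CPM, 3.24 ± 0.28, adjusted p = 7.34e-05). Glt28d2 (3.20), Adgra1 (3.12 ± 0.32, adjusted p = 0.000306), the serine protease gene Htra1 (2.87), Rgl3 (2.86), the zinc-finger gene Zbtb46 (33.4 ± 0.504 against 4.63 ± 0.251 CPM, 2.85 ± 0.23, adjusted p = 6.72e-05) and Aldh1l1 (2.69) followed. Dmrt3, a transcription factor gene of the dorsomedial telencephalon, fell most among the named genes (1.33 ± 0.813 against 7.58 ± 1.37 CPM, -2.73 ± 0.38, adjusted p = 0.00237). Lhx5 (-2.50), Apobec1 (-2.28), Doc2b (-2.03), Ddr2 (-1.96), the proneural gene Neurog1 (-1.91) and Sla (65.9 ± 8.20 against 234.0 ± 13.3 CPM, -1.83 ± 0.32) fell too. Reln, Aldh1l1, Glt28d2, Lhx5, Doc2b and Ddr2 share exonic bases with other transcripts.

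Of 8 Cajal-Retzius genes Reln, Lhx5 and Ndnf (-1.52 ± 0.27) fell (4 adjusted over the list alone), and the set was lower (camera, adjusted p = 1.06e-07, and adjusted p = 0.0558 with an estimated correlation). Of 28 axon guidance genes Slit2 and Sema3c (1.88 ± 0.27) rose (6 adjusted over the list alone; adjusted p = 0.000267, and adjusted p = 0.42 with an estimated correlation). Of 16 GABAergic genes the neuropeptide gene Npy rose (1.61 ± 0.25; 1 adjusted over the list alone; adjusted p = 1.93e-05, and adjusted p = 0.457 with an estimated correlation), and of 15 upper-layer genes Dkk3 rose (1.06 ± 0.23; 2; adjusted p = 0.00485, and adjusted p = 0.42 with an estimated correlation). The cell cycle set was lower, with Ccnd2, a cyclin gene of cortical progenitors, down (-0.67 ± 0.13, 1 of 26; 1; adjusted p = 1.66e-06, and adjusted p = 0.683 with an estimated correlation). The radial glia set was lower while Lhx2, a cortical selector gene, rose (0.58 ± 0.13, 1 of 16; 1 rose and 1 fell adjusted over the list alone; adjusted p = 0.0256, and adjusted p = 0.683 with an estimated correlation). The layer 6 set was lower, with Tle4 down (1 of 9; 2; adjusted p = 0.0131, and adjusted p = 0.512 with an estimated correlation).

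Other lists of the E15.5 Bcl11a-CKO had no call for the set. Of 12 intermediate progenitor genes, Insm1 (0.48 ± 0.10) and Eomes (0.59 ± 0.14) rose and Neurog1 and Gadd45g (-0.54 ± 0.11) fell (4 rose and 3 fell adjusted over the list alone). Of 6 subplate genes, Nxph4 rose (0.65 ± 0.14) and Nr4a2 and Lpar1 (-1.02 ± 0.17) fell (1 and 2). Of 7 astrocyte genes, Aldh1l1 and Gfap (2.74 ± 0.61) rose and Aldoc (-0.93 ± 0.19) fell (3 and 1). Neurod1, a neuronal differentiation factor, rose among 16 pan-neuronal genes (0.70 ± 0.16; 2 and 1). No gene passed in the layer 5 (1 fell adjusted over the list alone), thalamus (1 rose and 1 fell), microglia (1 rose), p53 and apoptosis, striatal, hippocampal, oligodendrocyte, endothelial, meningeal, erythroid or immediate early lists.

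With 2 units in each group, every left-out unit lowered the count of 289 for the E15.5 Bcl11a-CKO: to 57 without control replicate 1, 102 without control replicates 2 and 3, 68 without Bcl11a-CKO replicate 1, and 86 without Bcl11a-CKO replicates 2 and 3, where the remaining unit is taken to vary like the other groups. Reln, Tle4, Slit2, Dhrs3, Adgra1 and Zbtb46 kept their calls in each case, and Dmrt3 and Lhx5 lost theirs without Bcl11a-CKO replicates 2 and 3 (adjusted p = 0.0762 and 0.0733). Nr4a2 lost its call without Bcl11a-CKO replicate 1 or replicates 2 and 3 (adjusted p = 0.0596 and 0.0575). Without control replicate 1 the adjusted p was 0.0506 for Sema3c and Ndnf, 0.0626 for Npy, 0.117 for Cdh23, 0.273 for Dkk3, 0.12 for Ccnd2 and 0.201 for Lhx2. It was 0.193 for Glt28d2, 0.103 for Htra1, 0.0766 for Rgl3, 0.0885 for Apobec1, 0.134 for Ddr2 and for Aldoc, 0.156 for Neurog1 and 0.078 for Sla. Among list members it was 0.214 for Eomes, 0.134 for Insm1, 0.107 for Gadd45g, 0.0616 for Lpar1, 0.26 for Nxph4, 0.0648 for Aldh1l1, 0.25 for Gfap and 0.0821 for Neurod1. Doc2b did not pass without Bcl11a-CKO replicates 2 and 3 (0.106).

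The E15.5 Bcl11ab-DCKO had the most genes called of the embryonic comparisons with control, and most genes of the layer 6 list fell. Of the 9 layer 6 corticothalamic genes 8 fell (8 adjusted over the list alone). Hs3st4 went from 107.3 ± 12.2 CPM in the control (n = 2) to 1.59 ± 0.142 in the mutant (n = 3; log2 fold change -6.07 ± 0.46, edgeR, adjusted p = 2.66e-06). Zfpm2 went from 69.2 ± 3.09 to 6.43 ± 2.18 CPM (-3.42 ± 0.21, adjusted p = 7.31e-08), Tle4 from 209.5 ± 30.4 to 38.9 ± 2.33 CPM (-2.43 ± 0.14, adjusted p = 4.29e-08) and Tshz3 from 118.8 ± 3.78 to 36.6 ± 0.781 CPM (-1.70 ± 0.18, adjusted p = 1.59e-05). The median over the list was -2.33, and the set test held with either correlation (camera, adjusted p = 6.74e-18, and adjusted p = 0.0241 with an estimated correlation). In all, 1235 genes rose and 1159 fell of 14947 tested.

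**Figure D2:**
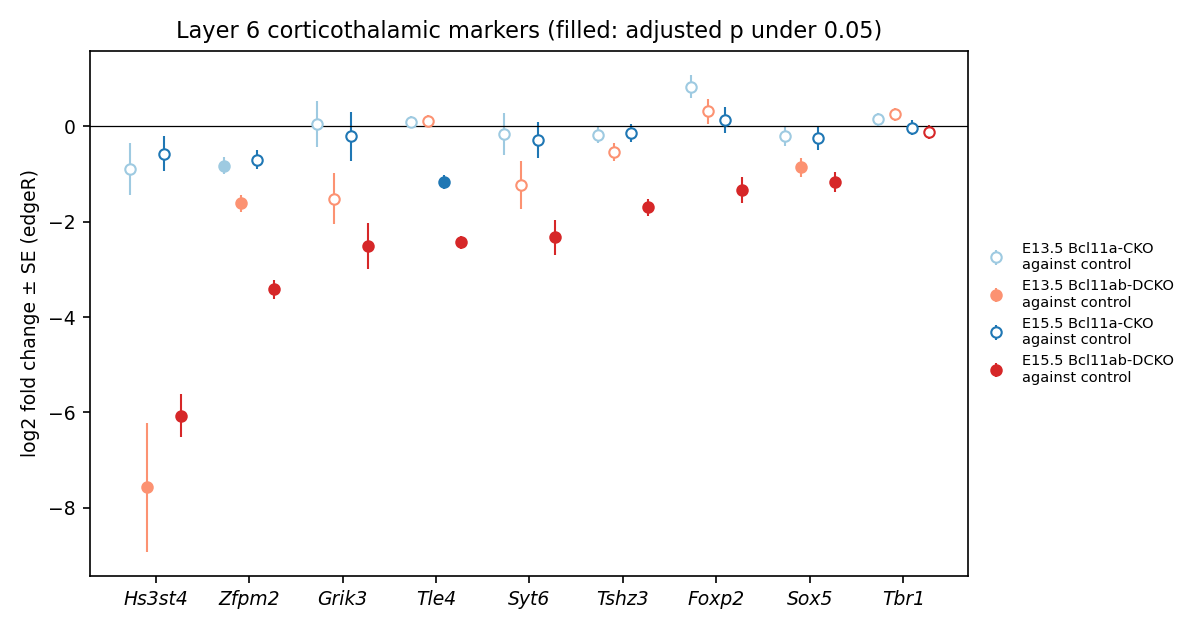
Log2 fold change ± SE against control of the 9 layer 6 corticothalamic genes at E13.5 and E15.5 in both mutants (edgeR). Filled points have an adjusted p under 0.05, and in the E15.5 Bcl11ab-DCKO 8 of the 9 genes lie below 0 with filled points, down to -6.07 for Hs3st4, whose E13.5 Bcl11ab-DCKO point is fitted from 0 counts and is no bound.

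Several genes with no counts in the E15.5 control appeared in the Bcl11ab-DCKO. The homeobox gene Uncx reached 13.4 ± 1.24 CPM (at least 60.3-fold higher), the nuclear receptor gene Esrrb 11.4 ± 2.40 (at least 51.8-fold) and the neurokinin B gene Tac2 7.94 ± 1.98 (at least 36.8-fold). The apolipoprotein gene Apob reached 6.49 ± 0.987 (at least 29.4-fold), the tight junction gene Cldn1 5.97 ± 0.555 (at least 26.7-fold) and Bves 5.49 ± 0.282 (at least 24.6-fold). Cdh23 rose from 0.793 ± 0.294 to 148.6 ± 26.9 CPM (7.60 ± 0.74, adjusted p = 7.63e-06), and Scube2 had 180 counts against 1 (ratio 143, 95% interval 25.3 to 5670). Besides Hs3st4, the largest falls were those of Egfl6 (79 counts in the control and 0 in the mutant, at least 33.2-fold lower), the thyroid hormone-binding gene Crym (165 against 2, ratio 104, 95% interval 28.3 to 866) and Mctp1 (120 against 3, ratio 50.4, 16.8 to 248). Hs3st3b1 (-5.93 ± 0.67), Nxph3 (1.43 ± 0.320 against 72.1 ± 8.42 CPM, -5.60 ± 0.36, adjusted p = 1.45e-07), Pappa2 (-5.09 ± 0.40) and Jakmip3 (-5.04 ± 0.49) fell too.

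Of 28 axon guidance genes 8 rose and 4 fell (9 and 4 adjusted over the list alone; camera, adjusted p = 0.00764, and adjusted p = 0.608 with an estimated correlation). Slit2 (chromosome 5, 47983138 to 48307733) rose from 11 ± 0.305 to 119.1 ± 1.58 CPM (3.43 ± 0.11, adjusted p = 5.48e-10) and Sema3c from 34.9 ± 4.40 to 328.6 ± 28.0 CPM (3.22 ± 0.26). The semaphorin receptor gene Plxna4 rose (1.83 ± 0.22) and the ephrin receptor gene Ephb1 fell (-2.94 ± 0.15, adjusted p = 2e-08). Of 8 Cajal-Retzius genes Reln (-1.70 ± 0.14), Ndnf (-2.32 ± 0.26), Lhx5 (-1.86 ± 0.30) and Ebf3 (-0.78 ± 0.24) fell (5; adjusted p = 6.26e-05, and adjusted p = 0.0904 with an estimated correlation). Of 26 cell cycle genes 6 fell (9; adjusted p = 0.000428, and adjusted p = 0.776 with an estimated correlation), with Ccnd2 (-0.88 ± 0.12) and Ccnb1 (-0.69 ± 0.15) among them. Of 11 microglia genes the receptor genes Csf1r (0.71 ± 0.11) and P2ry12 (0.71 ± 0.21) rose (4; adjusted p = 0.046, and adjusted p = 0.512 with an estimated correlation).

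Deep- and upper-layer genes other than those of layer 6 went both ways in the E15.5 Bcl11ab-DCKO. Of 10 layer 5 genes 2 rose and 4 fell (3 and 5 adjusted over the list alone): Fezf2 fell from 246.0 ± 15.5 to 95.9 ± 5.22 CPM (-1.36 ± 0.11, adjusted p = 1.56e-06) and Otx1 fell (-0.92 ± 0.12), while Pcp4 rose (1.59 ± 0.28). Of 15 upper-layer genes 5 rose and 2 fell (5 and 4), with Pou3f1 (1.44 ± 0.27), Dkk3 (1.38 ± 0.22) and Lmo4 (1.03 ± 0.21) up and Rorb, a layer 4 gene, down (-2.09 ± 0.23). Of 16 pan-neuronal genes 4 rose and 6 fell (4 and 7): Neurod1 (1.68 ± 0.15) and Slc17a6 (1.31 ± 0.13) rose, and Slc17a7 (-1.63 ± 0.18) and the synaptic gene Snap25 (-1.79 ± 0.23) fell. Of 12 intermediate progenitor genes 5 rose and 1 fell (5 and 3), with Eomes (0.80 ± 0.13), Insm1 (0.57 ± 0.09), Mfng (0.62 ± 0.10) and Sstr2 (1.05 ± 0.18) up. Of 16 radial glia genes Lhx2 rose (0.66 ± 0.12) and 3 fell (1 and 5), led by Ptprz1 (-1.25 ± 0.11). Of 6 subplate genes Nxph4 rose (0.80 ± 0.13) and Nr4a2 (-1.70 ± 0.26) and Lpar1 (-1.03 ± 0.15) fell (1 and 2).

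In the remaining lists, the p53 targets Cdkn1a (0.93 ± 0.20), Phlda3 (0.87 ± 0.26) and Sesn2 (0.94 ± 0.28) rose and Zmat3 (-0.38 ± 0.10) fell among 15 p53 and apoptosis genes (3 and 1). The interneuron genes Sst (1.37 ± 0.31) and Slc32a1 (0.96 ± 0.30) were among the 3 that rose of 16 (3). Meis2 (0.88 ± 0.08) and Ebf1 (1.95 ± 0.37) rose and Ppp1r1b (-2.40 ± 0.39) and the dopamine receptor gene Drd1 (-2.14 ± 0.47) fell of 8 striatal genes (2 and 2). Lef1 (1.03 ± 0.17) rose and Rspo3 (-2.58 ± 0.35) fell of 5 genes of the hippocampus and cortical hem (1 and 1). The thalamus list had Slc17a6 and Lhx9 (2.84 ± 0.44) up and Foxp2, which the layer 6 list holds too, down (-1.33 ± 0.26) of 5 (2 and 1). Aldh1l1 (3.07 ± 0.39), the water channel gene Aqp4 (1.41 ± 0.33) and 1 more gene rose and Aldoc (-0.90 ± 0.17) and Sparcl1 (-1.04 ± 0.20) fell of 7 astrocyte genes (5 and 2). The activity-induced genes Npas4 (3.28 ± 0.47) and Nr4a1 (0.90 ± 0.25) rose of 7 immediate early genes (2). No oligodendrocyte, endothelial, meningeal or erythroid gene passed the test. Not every call that was lost when a unit was left out is listed below.

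Leaving out control replicate 1 lowered the count of 2394 genes for the E15.5 Bcl11ab-DCKO to 1400, and leaving out control replicates 2 and 3 lowered it to 1319. Without control replicate 1 the adjusted p was 0.27 for Ebf3, 0.196 for Nr4a1, 0.177 for Sesn2, 0.188 for P2ry12 and 0.201 for Slc32a1. It was 0.0577 for Sst, 0.0649 for Phlda3 and 0.0626 for Lmo4, and without control replicates 2 and 3 it was 0.0936 for Cdkn1a, 0.17 for Zmat3, 0.143 for Aqp4, 0.0854 for Drd1 and 0.0517 for Sparcl1.

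**Figure D3:**
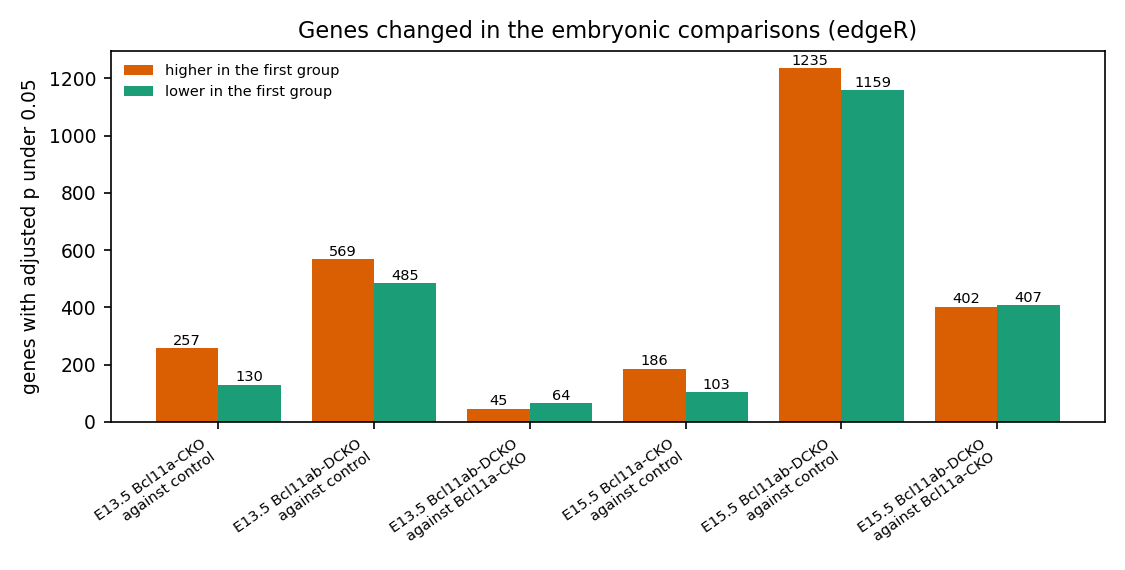
Number of genes with an adjusted p under 0.05 (edgeR, 14947 tested) in each embryonic comparison, with bars from 0 for genes higher and lower in the first group named. The tallest bars are those of the E15.5 Bcl11ab-DCKO against control, at 1235 and 1159.

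Between the mutants at E15.5, 402 genes were higher and 407 lower in the Bcl11ab-DCKO (n = 3) than in the Bcl11a-CKO (n = 2; edgeR, 14947 tested). Of the 9 layer 6 genes 8 were lower (8 adjusted over the list alone; camera, adjusted p = 3.03e-22, and adjusted p = 0.0189 with an estimated correlation), with Hs3st4 at 1.59 ± 0.142 against 72.0 ± 9.20 CPM (-5.49 ± 0.46, adjusted p = 1.58e-05). Uncx was at least 60.4-fold higher in the double mutant, and the retinoic acid hydroxylase gene Cyp26b1 had 167 counts against 3 (ratio 44.2, 95% interval 14.9 to 217). Scube2 (5.04 ± 0.42), Rasal1 (4.97 ± 0.56) and Mycbpap (4.46 ± 0.69) were higher too. Crym (63 counts in the Bcl11a-CKO against 2, ratio 39.7, 10.5 to 335), Mctp1 (96 against 3, ratio 40.3, 13.4 to 199), Hs3st3b1 (-4.73 ± 0.73) and Pappa2 (-4.42 ± 0.41) were lower. Of 10 layer 5 genes 1 was higher and 2 lower (2 and 4 adjusted over the list alone; adjusted p = 0.0395, and adjusted p = 0.25 with an estimated correlation). The count of 809 genes went to 418 without Bcl11a-CKO replicate 1 and 353 without Bcl11a-CKO replicates 2 and 3, where Cyp26b1 did not pass (adjusted p = 0.0564). Crym did not pass without Bcl11a-CKO replicate 1 or Bcl11ab-DCKO replicate 2 (adjusted p = 0.11 and 0.064).

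Many genes were called in the same direction in both mutants. At E13.5, 211 genes rose and 97 fell in both, and 0 went opposite ways, where lists drawn independently would share 9.78 and 4.22. At E15.5 the numbers were 167 and 96, with 0 opposite, against 15.4 and 7.99. Unchanged groups simulated around the control means, with simulated controls common to both, shared 0 and 0 calls at each age (10 simulations). With no gene changed, hardly any call can arise, so these values are no reference for the number of shared calls. The covariance of the fold changes across genes, which are not independent replicates, was 0.191 at E13.5 against 0.0534 simulated, and 0.277 at E15.5 against 0.0697 (r 0.68 against 0.524, and 0.622 against 0.54). The controls are too few to split, so part of the excess may come from the shared control libraries. Between ages, 62 genes rose and 26 fell at both in the Bcl11a-CKO with 1 opposite (3.2 and 0.896 for independent lists), and 327 rose and 231 fell in the Bcl11ab-DCKO with 35 opposite (47 and 37.6).

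The change of effect between E13.5 and E15.5 was tested as an interaction. In the Bcl11a-CKO it involved 12 genes, 5 with a higher and 7 with a lower effect at E15.5 (edgeR, 14947 tested). Slit2 was unchanged at E13.5 by its test (0.02, adjusted p = 0.957) and rose at E15.5, a difference of 1.09 ± 0.15 (adjusted p = 0.0119), and Tle4 went from 0.09 (adjusted p = 0.795) to -1.16 (difference -1.25 ± 0.19, adjusted p = 0.026). The ryanodine receptor gene Ryr3 went from 1.52 to -0.30 (difference -1.82 ± 0.21, adjusted p = 0.00321) and Ndnf from 1.21 to -1.52 (-2.72 ± 0.41, adjusted p = 0.0254). In the Bcl11ab-DCKO the effect of 309 genes was higher and of 270 lower at E15.5. Ephb1 rose at E13.5 (0.81, adjusted p = 0.00209) and fell at E15.5 (-2.94), a difference of -3.76 ± 0.20 (adjusted p = 2.16e-07).

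As sets, layer 6 genes (4 of 9 lower in effect, 4 adjusted over the list alone; camera, adjusted p = 2.18e-09, and adjusted p = 0.089 with an estimated correlation) and Cajal-Retzius genes (3 of 8, 4; adjusted p = 2.26e-05, and adjusted p = 0.089 with an estimated correlation) were lower in effect at E15.5 than at E13.5 in the Bcl11ab-DCKO. So were cell cycle genes (1 of 26, 1; adjusted p = 0.00197, and adjusted p = 0.778 with an estimated correlation), while the axon guidance set was called higher in effect with members going both ways (5 higher and 4 lower of 28, 9 and 4; adjusted p = 0.0409, and adjusted p = 0.683 with an estimated correlation). In the Bcl11a-CKO, the Cajal-Retzius set (1 of 8, 3; adjusted p = 2.84e-05, and adjusted p = 0.0904 with an estimated correlation) was lower in effect at E15.5. So were intermediate progenitor (0 of 12, 1; adjusted p = 0.0132, and adjusted p = 0.609 with an estimated correlation) and subplate genes (0 of 6; 1 higher and 3 lower; adjusted p = 0.0132, and adjusted p = 0.181 with an estimated correlation). Immediate early genes were higher in effect (0 of 7, 1; adjusted p = 0.0384, and adjusted p = 0.372 with an estimated correlation). The count of 12 genes went to 19 without E13.5 Bcl11a-CKO replicate 1, 6 without E13.5 Bcl11a-CKO replicate 3, 4 without E15.5 control replicate 1, 2 without E15.5 Bcl11a-CKO replicate 1 and 5 without E15.5 Bcl11a-CKO replicates 2 and 3. Slit2 lost its call without E15.5 Bcl11a-CKO replicate 1, control replicate 1 or control replicates 2 and 3 (adjusted p = 0.0571, 0.0797 and 0.0562), and Tle4 (0.169) and Ndnf (0.169) without E15.5 Bcl11a-CKO replicates 2 and 3. The count of 579 went to 377 without E13.5 Bcl11ab-DCKO replicate 2, 309 without E15.5 control replicate 1 and 295 without E15.5 control replicates 2 and 3.

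At P0, the Bcl11a-CKO differed from control in a subplate gene, 2 striatal genes and calretinin. Nr4a2 (chromosome 2, 57106830 to 57124003) fell from 101.9 ± 9.39 to 2.00 ± 0.207 CPM (n = 3 each, log2 fold change -5.10 ± 0.12, limma, adjusted p = 7.76e-08). Calb2, which encodes calretinin, rose from 5.50 ± 0.718 to 58.3 ± 3.69 CPM (3.19 ± 0.12, adjusted p = 1.19e-06). Sema3c rose from 56.6 ± 6.23 to 144.4 ± 11.5 CPM (1.34 ± 0.10, adjusted p = 6.49e-05). Among the 12576 genes tested, 26 rose and 44 fell, which is the count among the genes held and not the number that changed. The titles of the P0 Bcl11a-CKO libraries carry a code that the titles of the other P0 libraries lack. Its meaning is not given, so an effect of what it marks cannot be told from one of genotype.

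The other genes that rose most were Hba-a2 (164.4 ± 17.6 against 1.28 ± 0.442 CPM, 6.20 ± 0.16), and mt-Atp8 (384.3 ± 43.0 against 16.3 ± 1.13 CPM, 4.47 ± 0.10). Among the genes that the naming rule took, they were followed by Sypl2 (2.96 ± 0.15), Rn18s-rs5 (2.32 ± 0.09), the integrin gene Itga9 (2.32 ± 0.15), the glyoxalase gene Glo1 (2.26 ± 0.14) and the ribosomal protein gene Rpl26 (2.23 ± 0.10). Hba-a2 and Rn18s-rs5 share 92.3% and 71.9% of their 31-mers with other genes, mt-Atp8 overlaps mt-Atp6, and Glo1 shares exonic bases with 1700097N02Rik, so these are uncertain. The retinoid receptor gene Rxrg (-3.35 ± 0.28), Ebf1 (-3.25 ± 0.25), the retinoic acid-binding gene Crabp1 (-3.16 ± 0.20), Nexn (-2.94 ± 0.20) and the dendritic gene Ddn (-2.79 ± 0.22) fell, as did Gdf1 (-2.96 ± 0.21), which overlaps Cers1, shares 100% of its 31-mers with other genes and is uncertain. In the striatal list Ebf1 and the substance P precursor gene Tac1 (-2.73 ± 0.18) fell of 5 tested (3 adjusted over the list alone). Reln fell (-1.32 ± 0.10) and Calb2 rose, the 2 Cajal-Retzius genes tested (1 and 1), and Calb2, which the thalamus list holds too, was the call among its 3 (1). Plxnd1 fell (-1.59 ± 0.14, 1 of 8 upper-layer genes; 1), Nr4a2 was the subplate call (1 of 5; 1 rose and 3 fell), Sema3c the axon guidance call (1 of 17; 5 rose and 1 fell), and Hba-a2 the erythroid call (1 of 4; 1). The other erythroid genes tested, Hbb-bs (-0.10), Hbb-bt (0.01) and Alas2 (0.54), did not pass, so Hba-a2 did not move with the list. No gene passed among 3 layer 6 (1 fell adjusted over the list alone), 13 radial glia (1 rose and 2 fell), 24 cell cycle (2 rose) and 7 intermediate progenitor genes (1 rose). The same held for 15 p53 and apoptosis, 7 layer 5, 9 pan-neuronal, 7 GABAergic, 4 hippocampal, 1 choroid plexus, 6 oligodendrocyte, 5 astrocyte, 10 microglia, 9 endothelial, 7 meningeal and 4 immediate early genes. Genes with p in the gap are missing, and each adjusted p depends on them, so these lists are not shown to be unchanged. The meningeal genes were higher without passing, alone or adjusted over the list, from 0.08 ± 0.53 for Foxd1 to 2.05 ± 1.06 for Col3a1. The count of 70 went to 260 without control replicate 2, of which 191 rose and 69 fell, so the balance of directions rests on that library. With DESeq2 on the recovered reads it was 1283, of which 654 rose and 629 fell. It went to 109 without control replicate 3, and to 38 without genes that share at least 50% of their 31-mers with another gene, an alternative added after seeing the data.

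The P0 control libraries stood apart from the others in mt-Atp8 and Hba-a2. The mitochondrial gene mt-Atp8, at 16.3 ± 1.13 CPM in the P0 control, lay between 554.5 and 608.9 CPM in every embryonic group mean. Hba-a2 was at 1.28 CPM there, against 152.8 and 70.6 CPM in the E13.5 and E15.5 controls. Xist was at 1.21 to 2.07 CPM in all 3 P0 control libraries and at 2431 to 3148 CPM in the Bcl11ab-DCKO, and the Y-linked gene Ddx3y was at 0.138 CPM in 1 control library, replicate 3, and at 63.8 and 75.9 CPM in the others. Xist thus separated the control from the Bcl11ab-DCKO in full, so an effect of sex on the P0 Bcl11ab-DCKO comparison cannot be told from one of genotype. In the P0 Bcl11a-CKO Ddx3y was at 50.5 CPM in 1 library and at 0 and 0.042 in the other 2, so sex was not balanced there either. Control replicate 3 was low in both genes, which leaves its label and its sex in doubt. Low Xist thus does not show that all 3 control libraries came from males. Malat1 was at 591.1 ± 83.8 CPM in the P0 Bcl11a-CKO, against 217.5 ± 28.4 in the P0 control and 209.5 to 282 in the embryonic group means. It has no value here for the P0 Bcl11ab-DCKO, so whether the Bcl11a-CKO alone stood apart at P0 cannot be told. Meningeal genes differed widely between libraries within the control and within the Bcl11ab-DCKO, and less within the Bcl11a-CKO. Col3a1 was at 1.90, 113.6 and 38.9 CPM in control replicates 1, 2 and 3, at 89.3, 116.4 and 87.4 in the Bcl11a-CKO, and at 66.0, 0.794 and 0.867 in the Bcl11ab-DCKO.

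**Figure D4:**
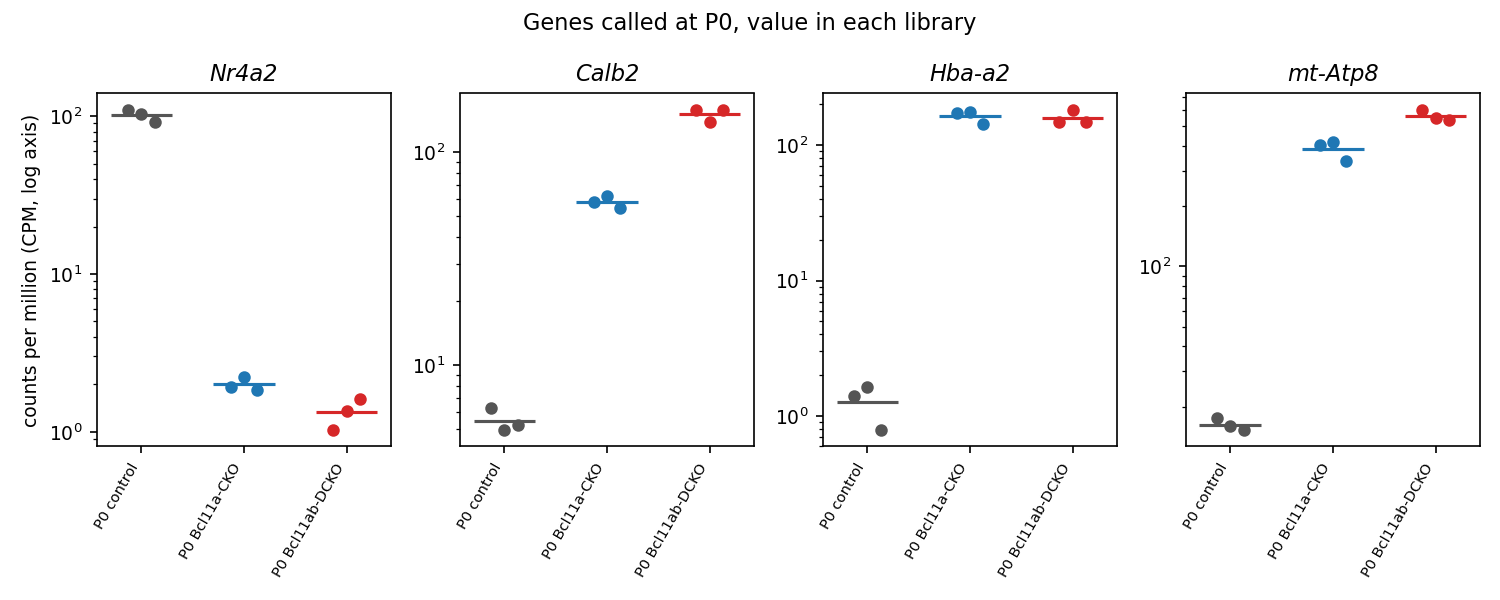
CPM of Nr4a2, Calb2, Hba-a2 and mt-Atp8 at P0 on log axes, with a point for each library and a bar for each group mean. Nr4a2 lies at 101.9 CPM on average in the control and under 3 CPM in every mutant library, while Hba-a2 and mt-Atp8 are at 1.28 and 16.3 CPM in the control and higher in both mutants.

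In the P0 Bcl11ab-DCKO, the layer 6 genes that could be tested were lower than in the control. Of the 9 in the list 5 were tested and all 5 fell (5 adjusted over the list alone), in a table that leaves out genes by their p-value. Hs3st4 fell from 109.1 ± 17.3 to 4.90 ± 1.62 CPM (n = 3 each, log2 fold change -4.25 ± 0.22, limma, adjusted p = 6.18e-06). Foxp2 fell from 64.1 ± 11.6 to 4.18 ± 1.37 CPM (-3.67 ± 0.20) and Tle4 from 153.7 ± 24.2 to 20.3 ± 0.414 CPM (-2.85 ± 0.11). Syt6 (-2.68 ± 0.10) and Sox5 (from 210.6 ± 25.0 to 51.7 ± 4.42 CPM) fell too. Eomes rose from 11 ± 1.56 to 74.1 ± 6.82 CPM (2.65 ± 0.12, adjusted p = 3.89e-06), the call among 3 intermediate progenitor genes (1). Calb2 rose to 151.5 ± 11.3 CPM (4.56 ± 0.11, adjusted p = 1.82e-07) and Nr4a2 fell to 1.33 ± 0.30 CPM (-5.47 ± 0.14). Among the 7404 genes tested, 16 rose and 54 fell, again the count among the genes held, and Xist went with genotype in this comparison.

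Cldn1 (3.23 ± 0.19), the glycine decarboxylase gene Gldc (2.30 ± 0.14), the neurotrophic receptor gene Gfra2 (2.24 ± 0.13) and Fgfr1 (281.7 ± 12.5 against 68.9 ± 6.54 CPM, 2.02 ± 0.08) rose. So did Hba-a2 (6.15 ± 0.17) and mt-Atp8 (562.1 ± 36.8 against 16.3 ± 1.13 CPM), uncertain as above, while the overlapping mt-Atp6 was at 1418 ± 96.7 CPM in the control and 1343 ± 40.6 in the mutant. The relaxin receptor gene Rxfp1 (-4.12 ± 0.17), the tyrosine kinase gene Ptk2b (-3.93 ± 0.13), Npas2 (-3.83 ± 0.19) and Fam19a1 (-3.77 ± 0.21) fell. Reln fell (-1.84 ± 0.10) and Calb2 rose among 3 Cajal-Retzius genes (1 and 1), and Calb2 rose and Foxp2 fell among 3 thalamus genes (1 and 1). Rorb (-2.78 ± 0.12, 1 of 2 upper-layer genes; 1), Ephb1 (-2.43 ± 0.12, 1 of 5 axon guidance genes; 1), and the neurofilament gene Nefl (-2.53 ± 0.15, 1 of 3 pan-neuronal genes; 1) fell. So did Npy (-3.27 ± 0.20, 1 of 7 GABAergic genes; 1), Ppp1r1b (-2.58 ± 0.14, 1 of 2 striatal genes; 1) and Nr4a2 (1 of 3 subplate genes; 1). Hba-a2 was the erythroid call (1 of 2; 1). No gene passed among 3 radial glia, 21 cell cycle, 6 p53 and apoptosis, 2 layer 5, 1 hippocampal, 1 choroid plexus, 2 oligodendrocyte, 2 astrocyte, 1 microglia, 3 endothelial, 4 meningeal and 1 immediate early genes. Held genes other than the 70 with the smallest p had a p of at least 0.054 (edgeR's exact test), so they could hardly pass. These lists are therefore not shown to be unchanged.

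Both P0 tables hold genes by their p against the same control, so the counts and list shares between the mutants are shaped by this selection. In the Bcl11ab-DCKO table, all but 70 genes had a p of at least 0.054 against control (edgeR's exact test). The numbers below are thus no measure of what the loss of Bcl11b adds. Between the mutants at P0, over the 6905 genes tested that both tables hold, 101 were higher and 176 lower in the Bcl11ab-DCKO (n = 3 each, limma). With the libraries shifted to the same median the split was 164 higher and 66 lower, so the direction of the balance rests on the scaling. Tle4 was lower (20.3 ± 0.414 against 122.1 ± 1.76 CPM, -2.53 ± 0.10, adjusted p = 1.73e-07), as were Fam19a1 (-3.71 ± 0.18), Ptk2b (-3.55 ± 0.10), Npy (8.93 ± 3.05 against 85.8 ± 11.5 CPM, -3.16 ± 0.19) and Rorb (-2.49 ± 0.11). Calb2 (1.36 ± 0.10, adjusted p = 1.4e-05), Rasa4 (1.20 ± 0.22), Spint2 (1.16 ± 0.21), the cartilage collagen gene Col2a1 (1.07 ± 0.22) and Nhlh2 (0.81 ± 0.15) were higher. None of the 4 meningeal genes tested passed the test, but all 4 were lower adjusted over the list alone, with Col3a1 at -4.01 ± 1.44 and Col1a1 at -3.38 ± 1.47. So were 2 of 3 endothelial genes, so marker genes of other tissue moved with this comparison. Of the other lists, 1 of 20 cell cycle (1 adjusted over the list alone), 1 of 6 p53 and apoptosis (2), 1 of 1 layer 6 (1), 1 of 2 upper-layer (1) and 1 of 4 GABAergic genes (1) were lower. In the thalamus list 1 of 2 was higher (1), and of 2 Cajal-Retzius genes 1 was higher and 1 lower (1 and 1). Adjusted over the list alone, 2 of 2 subplate, 2 of 3 axon guidance, 1 of 2 oligodendrocyte and 1 of 2 astrocyte genes were lower and 1 of 1 striatal gene higher. No other list had a call. The count of 277 went to 31, 31 and 36 without Bcl11a-CKO replicates 1, 2 and 3 and to 28 and 25 without Bcl11ab-DCKO replicates 2 and 3, and without Bcl11ab-DCKO replicate 3 the adjusted p was 0.0988 for Rasa4, 0.101 for Spint2, 0.115 for Col2a1 and 0.104 for Nhlh2.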

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

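The test on shared 31-mers and the test on striatal markers were chosen after their results were seen; the overlap test, the delay test and the splits were set before. The effect of each genotype was compared between E13.5 and E15.5 by an interaction test in edgeR, which gave 12 genes for the Bcl11a-CKO and 579 for the Bcl11ab-DCKO. The count of 12 went to 19 without E13.5 Bcl11a-CKO replicate 1, to 6 without E13.5 Bcl11a-CKO replicate 3, to 4 without E15.5 control replicate 1, to 2 without E15.5 Bcl11a-CKO replicate 1 and to 5 without E15.5 Bcl11a-CKO replicates 2 and 3. The count of 579 went to 377 without E13.5 Bcl11ab-DCKO replicate 2, 309 without E15.5 control replicate 1 and 295 without E15.5 control replicates 2 and 3.

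In the Bcl11a-CKO, the log2 effect was higher at E15.5 than at E13.5 by 1.71 for Eya1, 1.61 for Clmn, 1.09 for Slit2, 1.03 for Nt5dc2 and 0.60 for Cul7. It differed by -2.72 for Ndnf, -1.82 for Ryr3, -1.77 for Galnt14, -1.25 for Tle4 and -1.21 for Pde1c. Nt5dc2, Ryr3 and Galnt14 share exonic bases with other genes and are uncertain, as are Spp1, Kcnab1 and Ephb1 below. Nt5dc2 and Ryr3 kept their calls whichever unit was left out, and without E15.5 Bcl11a-CKO replicate 1 the adjusted p was 0.261 for Eya1, 0.151 for Clmn, 0.0571 for Slit2 and Cul7, 0.0551 for Ndnf and Galnt14, 0.0918 for Tle4 and 0.139 for Pde1c.

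In the Bcl11ab-DCKO, the fitted difference was 9.41 for Bves, 6.99 for Uncx, 6.07 for Spp1, 5.63 for Rasal1 and 5.01 for Fam135b, and -4.99 for Hs3st3b1, -4.82 for Kcnab1, -4.60 for Cntnap5b and -3.76 for Ephb1. Bves and Uncx had 0 counts in the E15.5 control, so their fitted values depend on the prior count and are no bounds. Spp1, Kcnab1, Cntnap5b and Ephb1 kept their calls whichever unit was left out. Without E13.5 control replicate 1 the adjusted p was 0.075 for Bves, 0.424 for Rasal1 and 0.0508 for Fam135b, without E15.5 control replicates 2 and 3 it was 0.105 for Uncx, and without E15.5 control replicate 1 it was 0.0541 for Hs3st3b1.

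At P0, 28 genes in the Bcl11a-CKO and 13 in the Bcl11ab-DCKO were at least 4-fold higher than in the control, among them Hba-a2 and mt-Atp8. Reads over overlapping genes counted differently in the control libraries would raise the odds of exonic overlap above 1.5 among them, and the odds ratios were 0.637 (95% interval 0.243 to 1.51) and 0.986 (0.253 to 3.42), so the explanation was not borne out and the intervals leave it open. Reads shared with near-identical genes are a candidate explanation for part of the pattern: 60.7% and 30.8% of these genes shared at least 50% of their 31-mers with another gene, against 4.8% and 6.04% of the others, odds ratios of 30.6 (13.5 to 72.8) and 6.92 (1.55 to 24.9). Shared sequence was not particular to genes that were higher. Of the genes at least 4-fold lower, 55.6% of 36 in the Bcl11a-CKO (odds ratio 24.9, 12.2 to 51.6) and 14.6% of 41 in the Bcl11ab-DCKO (2.67, 0.913 to 6.46) shared it too. Calb2, Sypl2, mt-Atp8, Cldn1 and Eomes are not covered by it. A difference between the genotypes, and in the Bcl11ab-DCKO the sex of the animals, stay open for the rest and were not tested apart. Col3a1, a meningeal gene among those of the Bcl11a-CKO, ranged from 1.90 to 113.6 CPM within the P0 control. For it, differences between the control libraries stay open too. For mt-Atp8, at 16.3 CPM in the P0 control and 554.5 to 608.9 CPM in every embryonic group mean, control and mutant alike, a fault of the P0 control libraries or their counting stays open too.

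The genes changed in the E15.5 Bcl11ab-DCKO were set against a delay in development. A delay would have at least 75% of the genes that fell rising from E13.5 to E15.5 in the Bcl11a-CKO libraries, and at least 75% of those that rose falling. Of the 1159 genes that fell, 57.4% rose with age (95% interval 54.5 to 60.2), and of the 1235 that rose, 40.4% fell with age (37.7 to 43.2), against 48.8% and 51.2% of all genes. These values argue against a delay as the whole explanation, because the genes that rose fell with age less often than all genes did. The genes that fell rose with age more often than all genes did, which is the direction of a delay. The values do not exclude a delay: signs were counted whether or not a gene changed with age, in libraries that are themselves mutant. Past the threshold with age in the direction of a delay were 41.7% of the genes that fell and 20.9% of those that rose. The share of all genes was not computed for this measure, so these percentages have no reference. The intervals treat genes as independent. A difference between the genotypes stays open and was not tested apart, and the tests say nothing about a delay in part of the genes.

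Striatal marker genes such as Ebf1 and Tac1 were far lower in the P0 Bcl11a-CKO, and striatal tissue in the control libraries would lower the whole list. The median over the members tested was -0.646, but 5 of the 12 members (41.7%) could be tested, which is too few to decide. Striatal tissue and an effect of the deletion cannot be told apart here.

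Splits of the 6 libraries into 3 and 3 are 10 in number, the real one included, too few for a share under 0.05. The real split gave 387 genes for the E13.5 Bcl11a-CKO (highest other 6; 1 of 10 as large), 1054 for the E13.5 Bcl11ab-DCKO (1; 1 of 10), 109 between the mutants at E13.5 (4; 1 of 10), 70 for the P0 Bcl11a-CKO (6; 1 of 10) and 277 between the mutants at P0 (1; 1 of 10). For the P0 Bcl11ab-DCKO it gave 70, and another split gave 77, so 2 of the 10 were as large. That split set Bcl11ab-DCKO replicate 1 with control replicates 2 and 3, the libraries where the meningeal gene Col3a1 was highest (66.0, 113.6 and 38.9 CPM). At P0, genes are missing by their p under the real grouping, so the count of the real split depends on which genes are held. The other P0 splits are not cut in this way, and no conclusion is drawn from setting them against the real one.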

How the results depend on the processing

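Chosen after seeing the data were the P0 edgeR test, the P0 tests without genes that overlap or share sequence, and the E13.5 tests without the libraries nearest to E15.5. Over 636 results of named genes, 8390 values were recomputed: 7861 stayed on the same side of the threshold, 404 fell short of it and 125 newly passed it. A reversal was counted only where the gene passed in either setting, and there were 0. Changes of sign among genes that passed in neither setting are within the 7861.

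With DESeq2, 231 genes differed between the mutants at E13.5 and 64 in the Bcl11a-CKO between ages, and at P0, on recovered reads, 1283 in the Bcl11a-CKO and 707 between the mutants. EdgeR on those reads gave 70, 70 and 219. The counts of 70 go with the gap in p, where genes are missing, and are no check of the calls. With a log2 fold change of at least 1 the counts were 121, 409 and 70 at E13.5 (Bcl11a-CKO, Bcl11ab-DCKO, between mutants), 144, 946 and 401 at E15.5, 333 for the Bcl11ab-DCKO between ages and 27 between the mutants at P0, by construction lower. From libraries of 1 age alone they were 176, 608 and 16 at E13.5 and 473 for the E15.5 Bcl11a-CKO. With each of 18 libraries as its own replicate, 646 genes changed in the E15.5 Bcl11a-CKO and 52 in the Bcl11a-CKO between ages. Without E13.5 control replicate 2 and Bcl11a-CKO replicate 1, 162 changed in the E13.5 Bcl11a-CKO and 28 in the Bcl11a-CKO between ages. At P0, 42 changed in the Bcl11ab-DCKO without overlapping genes, with 4520 of 7404 genes left to test. In the Bcl11a-CKO 38 changed without genes sharing 31-mers, with 11933 of 12576 left, so calls were frequent among the genes removed. With an estimated correlation 2 of 40 list calls held. Where no reason is given, the cause was not tested.

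Leaving out each library or unit in turn gave 184 to 484 genes for the E13.5 Bcl11a-CKO, 614 to 924 for the Bcl11ab-DCKO and 37 to 209 between them. At E15.5 it gave 57 to 102, 1319 to 1934 and 353 to 635, where a lone unit is taken to vary like the other groups. Between ages it gave 2 to 19 for the Bcl11a-CKO and 295 to 464 for the Bcl11ab-DCKO, and at P0 70 to 260, 70 to 73 and 25 to 204. Because genes with p in the gap are missing, P0 counts that stay near 70 say little about stability. No label says whether replicate numbers pair the P0 libraries. Deviations from the group means correlated at 0.159, 0.14 and 0.0912 between control and Bcl11a-CKO libraries of the same number, and at -0.24 to 0.145 between others. For the control and Bcl11ab-DCKO the values were -0.386, -0.398 and 0.049, and -0.376 to 0.486. Pairing is therefore left open, and as a block the numbers gave 71, 70 and 246 genes at P0. At E13.5, replicate 1 of each genotype carries the title suffix 1-2 and the others 1-8, whose meaning is not given. With this suffix as a block, 442 of 459 values of named genes stayed on their side of the threshold, 3 fell short of it and 14 newly passed it. Embryonic depth, from 4313142 to 7220708 counts, limits what can be said of genes near 0.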

Other observations

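This look at single libraries was chosen after their values were seen. Genes of the meninges varied widely between the P0 libraries of the control and of the Bcl11ab-DCKO, and less within the Bcl11a-CKO. Col3a1 lay at 1.90, 113.6 and 38.9 CPM in control replicates 1, 2 and 3, at 89.3, 116.4 and 87.4 CPM in the Bcl11a-CKO, and at 66.0, 0.794 and 0.867 CPM in the Bcl11ab-DCKO.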
